A study of Zea mays with 6 samples.

How the data were processed

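Radicle roots of the maize lines Huangzao4 and Mo17 were sampled 6 days after inoculation or mock treatment, and each of 6 groups, mock, P1 and P2 in each line, held 1 library, per the labels. The libraries were of short tags next to restriction sites, per the labels' protocols. The deposited tables gave, for each of 6 pairs of libraries, a gene identifier, a log2 fold change and a p-value, per the file headers. DESeq was the only tool named, without a version, per the submitters' processing notes. The tag mapping, the genome build, the scaling of the libraries and whether the p-values were adjusted are not given in the sources used here. In the deposited tables every log2 fold change was beyond 2 in size and every p-value under 0.01, so the tables held genes that had already passed these limits. Rows with no identifier numbered 128 in Mo17 P1 against mock, 31 in Mo17 P2 against mock and 8 in Huangzao4 P1 against P2, and were left out. An infinite log2 fold change was read as a level of 0 in 1 library, and no fold is given for it.

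The sign of the log2 fold change was not stated, and was read from genes at 0 in a library that 2 tables share, after 4 readings were tried. With inoculated over mock and P1 over P2, 46 of 62 such genes in Huangzao4 were at 0 in both tables, 74.2%, and 5 of 7 in Mo17. The reversed reading of all tables gave 13 of 32 and 2 of 9. The 16 contradicted Huangzao4 genes, GRMZM2G127087 (tps6/tps11) among them, were left in.

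The deposited p-values did not line up with the genes beside them. Of 252 neighbouring rows with equal p-values and finite fold changes, 65 had equal fold changes. Across genes higher than mock in both tables of a line, the fold changes of P1 and P2 had a Spearman rho of 0.70 in Huangzao4 (238 genes) and 0.47 in Mo17 (45 genes), and the p-values 0.18 and 0.24. Genes are not independent replicates, and both tables of a line share the mock library. The rho that p-values beside their own genes would have is unknown, so this gap alone does not show that they were out of line. Because equal p-values seldom stood beside equal fold changes, no p-value of a single gene is printed. The counts at p under 0.001 and the choice of named genes by p-value carry this doubt. Counts of genes, lists or overlaps at p under 0.001 can therefore not be read as a check of them.

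Gene names came from a RefSeq gene table of the assembly Zm-B73-REFERENCE-NAM-5.0, used for names only. Of 1761 identifiers listed in at least 1 table, 764 matched it, 43.4%, and 14 of these stood in more than 1 record. The 106 identifiers of BAC-clone form had no match, and 124 identifiers had a name other than a clone or locus number. Because names covered few genes and the table held no descriptions, the counts of gene lists cover only named members. Members were matched by name, so genes called ethylene-related are members of that list, mainly AP2/ERF genes with the symbol EREB.

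Computed here were the genes listed higher and lower in each table, the genes shared by pairs of tables and their directions, and counts of 25 gene lists fixed before the data were examined. A list with at least 5 members in a table was given the percentile of its median log2 fold change among 10000 random lists of the same size from that table. Matching on mean level, as planned, could not be done without levels. The code that joins 2 tables was run on simulated tables: with 200 planted shared genes among 34000, 205 shared genes were found, 201 of them in the same direction. The 200 genes were put into both tables, so this checks the code only. Counts, a shared mock library and ties were not simulated. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

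Named genes followed a rule fixed before the data were examined: per comparison the 8 largest rises and 8 largest falls among genes with a name, the 2 members with the lowest p-value of each list with at least 3 listed members, and up to 10 genes listed in both lines. The rule also asked for a mean level of at least 10 and a pseudocount of 1, which could not be applied without levels, so genes were ranked on the deposited log2 fold change and genes at infinite ratios named separately. It gave 28 genes in Huangzao4 P1, 30 in Huangzao4 P2, 19 in Mo17 P1 and 29 in Mo17 P2 against mock, and 16 and 12 in the direct comparisons of Huangzao4 and Mo17. Other members named beside a small count, such as BX14, TIFY10, PSBQ and fdx2, were chosen after their values were seen. Names of clone or accession form were removed from the rule, and 1 of several synonyms chosen for display, after the tables were seen. Not every gene of the rule is named in the text.

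Alternatives fixed before the data were examined were p under 0.001, at least 4-fold, a shift of every log2 fold change by 0.5, a mean level of at least 50 and pseudocounts of 1 and 10. Added after seeing the data were at least 8-fold, leaving out infinite ratios, a Benjamini-Hochberg threshold of 0.05 over the 34313 protein-coding reference genes, random lists drawn from genes of the same direction, and gene lists corrected by hand after names and values were seen. The Benjamini-Hochberg counts ranked only listed p-values. Genes under 4-fold were not in the tables, so the counts may be too low on that account. If the deposited p-values were already adjusted, these counts have no such meaning.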

Results

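The series followed radicle roots of maize (Zea mays) 6 days after inoculation with Sporisorium reilianum f. sp. zeae, the fungus of maize head smut, by sequencing short tags from messenger RNA. It set Huangzao4, a susceptible inbred line, beside Mo17, a resistant one. In each of the 2 lines there was 1 library of mock-treated roots, 1 of inoculated roots in which PCR did not detect the fungus (P1) and 1 of inoculated roots in which PCR detected it (P2), 6 libraries in all. P1 and P2 were therefore PCR outcomes, not times. The values came from the authors' own 6 pairwise tables, which listed genes with a log2 fold change beyond 2 in size and a p-value under 0.01. Levels, counts and library depths were not in these tables, so the depth behind each value is unknown. With 1 library per group no difference had a replicate check, no test of the conditions was run, and a gene outside a table is not shown to be unchanged. Direction was read as inoculated over mock and as P1 over P2, which the headers did not state.

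**Figure D1:**
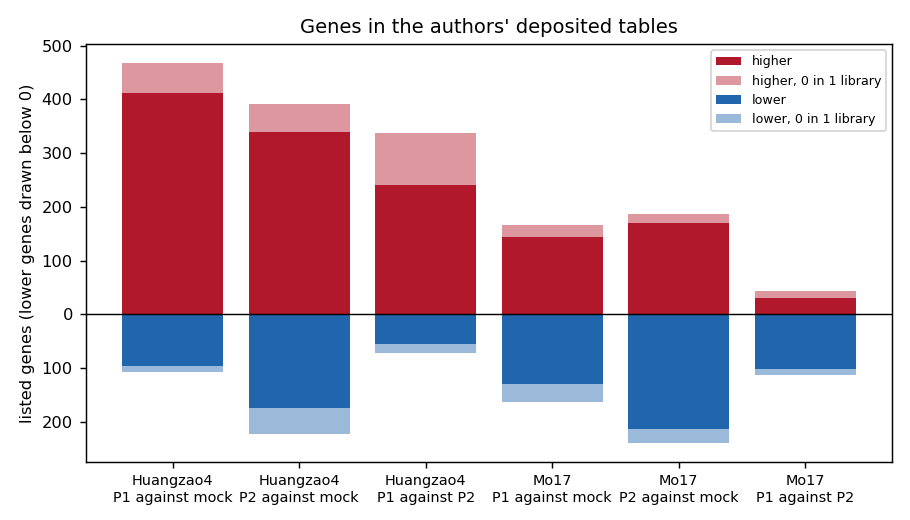
Bars give the number of genes in each of the authors' 6 deposited tables, with genes listed higher above 0 and genes listed lower below 0, and paler ends for genes listed at 0 in 1 of the libraries. Huangzao4 P1 had 468 higher and 108 lower genes against mock, while Mo17 P1 had 166 and 163.

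Which genes differed from mock in susceptible roots without detected fungus was asked with Huangzao4 P1. KSL4 (GRMZM2G016922), a kaurene synthase-like gene, had a log2 fold change of 5.16 and the cytochrome P450 gene CYP71Z16 (GRMZM2G067591) one of 4.38 in the authors' deposited table. The macrocarpene synthase identifier tps6/tps11 (GRMZM2G127087), which belongs to 2 reference records and so cannot be given to 1 gene, was listed at 0 in mock in the authors' deposited table. Its value in Huangzao4 P2 was finite, which puts the same mock library above 0, so it was 1 of the 16 contradicted genes. MYBR58, named as a MYB-related gene, was at 4.69, the laccase gene lac3 at 4.26 and the potassium transporter gene HAK5, which in P2 had the same fold change as a neighbouring identifier, at 4.10 in the authors' deposited table. In all, 468 genes were listed higher and 108 lower, of which 56 and 11 were at infinite ratios.

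Of the lists fixed before the data were examined, pathogenesis-related proteins had 5 of 5 listed members higher in the authors' deposited table of Huangzao4 P1. PR-1 was at 3.09, the chitinase gene chiI at 2.71, PR-5 at 2.52 and geb1, a glucanase gene also named pr6, at 2.47 in the authors' deposited table. Their median of 2.52 lay at percentile 35.1 of 10000 random lists of 5 genes from the same table, and at 14.2 of lists drawn from its higher genes alone. Of all genes listed in Huangzao4 P1 against mock 81.25% were higher, so small lists with most members higher do not stand out. Detoxification genes had 4 of 4 members higher, among them gst30 at 3.94 and gst24 at 2.87, both glutathione transferases, in the authors' deposited table. Transport genes had 2 of 3 members higher, the aquaporin genes NIP1-1 at 3.37 and TIP4-1 at 2.39, with NIP2-2 lower at -2.10, in the authors' deposited table, and 5 higher and 1 lower after correction by hand. Redox enzymes had 2 of 3 members higher in the authors' deposited table, Laccase-7, listed at 0 in mock, and the peroxidase gene PER70 at 2.58, with PER66 lower at -3.06, and 4 higher and 1 lower after correction by hand. Ethylene-related genes split evenly in the authors' deposited table, 2 higher and 2 lower, or 1 and 2 after correction by hand, and the lower ones were EREB68 at -2.34 and EREB36 at -2.33, of the AP2/ERF transcription factor family. The brassinosteroid synthesis gene Dwf4 at -2.13 and the dehydrin gene dhn1 at -2.24 were among the lower named genes of the authors' deposited table. The counts at p under 0.001 were 220 higher and 60 lower, and a Benjamini-Hochberg threshold over the reference genes kept 199 of the 576 genes. That threshold ranked only listed genes, so its counts may be too low. At p under 0.001, 2 pathogenesis-related members and 1 redox, 1 transport and 1 ethylene-related member were counted as higher. Here and in the comparisons below, counts by p-value carry the doubt on the p-values and do not check the lists.

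In susceptible roots with detected fungus, Huangzao4 P2 against mock, the authors' deposited table gave tps6/tps11 a log2 fold change of 5.85, KSL4 5.16 and CYP71Z16 4.61. For tps6/tps11 this finite value conflicts with the level of 0 in the same mock library that was read from Huangzao4 P1. The fixed list of terpenoid synthesis had 2 members in the authors' deposited table, both higher, tps6/tps11 and an2, a copalyl diphosphate synthase gene, at 2.38, and 4 higher members after correction by hand, with KSL4 and CYP71Z16. MYBR58 was at 4.24, the germin-like gene GLP2 at 3.73, and Laccase-7 was listed at 0 in mock in the authors' deposited table. The MYBR58 value was tied with that of AC206332.3_FG005. Altogether 391 genes were higher, 63.8% of those listed, and 222 lower.

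Pathogenesis-related proteins had 5 of 5 listed members higher in the authors' deposited table of Huangzao4 P2, with PR-5 at 3.50, chiI at 3.14, chiA at 2.57 and geb1 at 2.55, and their median of 2.57 was at percentile 59.0 of random lists and at 14.8 of lists of higher genes alone. Detoxification genes had 4 of 5 higher, with gst30 at 3.40 and gst24 at 2.87 and with cyp78 lower at -2.47, in the authors' deposited table, and their median was at percentile 74.3. Of 3 listed members of the transcription factor list MYBR58 was higher and 2 were lower, bHLH108 at -3.99 and NAC61 at -3.01, in the authors' deposited table. The bHLH108 value was tied with those of GRMZM2G014114 and GRMZM2G031986. The list went by name and did not hold all such genes, among them the AP2/ERF genes EREB179, higher at 2.83, and EREB68, lower, in the authors' deposited table. Of 4 members of the ethylene list 3 were lower in the authors' deposited table, ACS6, an aminocyclopropane carboxylate synthase gene, at -2.73, EREB68 at -2.63 and hap2, whose name is that of a CCAAT-binding factor and only looks ethylene-related, at -2.62. Among named genes with finite values the lowest were RCP1 at -5.02 and the growth-regulating factor gene GRF11 at -4.34, followed by bHLH108, in the authors' deposited table. The cytokinin response regulator crr5, whose identifier belongs to 2 reference records, was at -3.30 and AKHSDH1, an aspartate kinase and homoserine dehydrogenase gene, at -3.17 in the authors' deposited table. Listed at 0 in the P2 library in the authors' deposited table were his1, a histone H1 gene, pdi6, a protein disulfide isomerase gene, hsp22 and ZCN6. Of the seed storage markers, the globulin gene glb3 was lower at -3.28 in the authors' deposited table. At p under 0.001 the counts were 228 higher and 85 lower, and the Benjamini-Hochberg threshold kept 238 of 613 genes, with 3 pathogenesis-related members and 1 terpenoid gene left higher and 1 transcription factor left lower at p under 0.001.

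The same question in resistant roots without detected fungus, Mo17 P1, gave 166 genes higher and 163 lower, and the median log2 fold change of the higher genes was 2.54, against 3.10 in Huangzao4 P1, in the authors' deposited tables. These medians cover different genes, already cut at the limits of each table, so they do not compare the size of a response between the lines. The chitinase gene chiI at 3.00 and PR-5 at 2.78 were the 2 listed pathogenesis-related members, both higher, in the authors' deposited table. In2-1, a safener-induced gene, was at 2.54, tps6/tps11 at 2.36, gst24 at 2.18 and KSL4 at 2.12 in the authors' deposited table. Of the ethylene list 3 of 4 listed members were lower, with EREB68 at -3.63, EREB56 at -3.15 and EREB36 at -2.13 in the authors' deposited table, where EREB58 was listed at 0 in mock. All 4 were in that list by the symbol EREB alone. Also lower were AKHSDH1 at -3.25, the dihydroflavonol reductase gene A1 at -2.50, bx1, which opens benzoxazinoid synthesis, at -2.49 and TIFY4 at -2.12 in the authors' deposited table. The bZIP gene bzip1 was listed at 0 in the P1 library in the authors' deposited table. With p under 0.001, 30 genes were higher and 34 lower, and the Benjamini-Hochberg threshold kept 16 of 329, with 0 pathogenesis-related members higher and 0 ethylene-related members lower at p under 0.001.

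In resistant roots with detected fungus, Mo17 P2 against mock, all 5 listed pathogenesis-related proteins were higher, and 3 of 4 benzoxazinoid genes and 3 of 3 genes of the TIFY family, which holds jasmonate signalling repressors, were lower in the authors' deposited table. The authors' deposited table gave tps6/tps11 a log2 fold change of 5.06, the wound-induced inhibitor gene wip1 4.76 and the proteinase inhibitor gene MPI 4.02. The chalcone synthase gene whp1 was at 4.33, the tonoplast aquaporin gene TIP1-2 at 4.71 and ALDH12, whose identifier belongs to 2 reference records, at 4.78 in the authors' deposited table. In all, 186 genes were higher, 43.8% of those listed, and 239 lower.

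The pathogenesis-related members of the authors' deposited table of Mo17 P2 were chiI at 4.13, PR-1 at 3.61, PR-5 at 3.27, geb1 at 2.97 and chiA at 2.33, and their median of 3.27 was at percentile 88.8 of random lists, but at 33.7 of lists of higher genes alone, whose median was 3.58. The diterpenoid genes an2 and KSL4 were at 3.60 and 3.15 in the authors' deposited table. Benzoxazinoid genes had 3 of 4 members lower, BX4 at -3.46, bx1 at -3.34 and BX3 at -2.13, while BX14 was higher at 3.51 in the authors' deposited table. All 3 listed jasmonate members were lower, TIFY25 at -3.17, TIFY10 at -2.91 and TIFY20 at -2.72, in the authors' deposited table. None of 5 listed members of the ethylene list was higher in the authors' deposited table, where EREB65 was at -4.76 and EREB36 at -2.75. The list's median of -2.61 was at percentile 27.7, and at 79.5 of lists of lower genes alone. All 5 were AP2/ERF genes placed there by the symbol EREB, which does not by itself tie them to ethylene. Detoxification genes had 3 of 4 lower in the authors' deposited table, but these included BX3 and BX4, counted above, and the glutathione transferase gene gst31 was higher at 2.48, and correction by hand left 2 higher and 2 lower. Lower as well were the auxin transporter gene PIN5c at -3.89 and the photosystem I gene psaN at -4.48 in the authors' deposited table. Listed at 0 in the P2 library of the authors' deposited table were ZCN8, a FLOWERING LOCUS T relative, and the zein gene gz16, a seed storage marker. At p under 0.001 the counts were 47 higher and 63 lower, and the Benjamini-Hochberg threshold kept 19 of 425 genes, while the list counts fell to 0 pathogenesis-related members higher and to 1 benzoxazinoid, 0 jasmonate, 1 ethylene-related and 1 detoxification member lower at p under 0.001. With at least 8-fold the balance turned, to 132 higher and 113 lower.

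**Figure D2:**
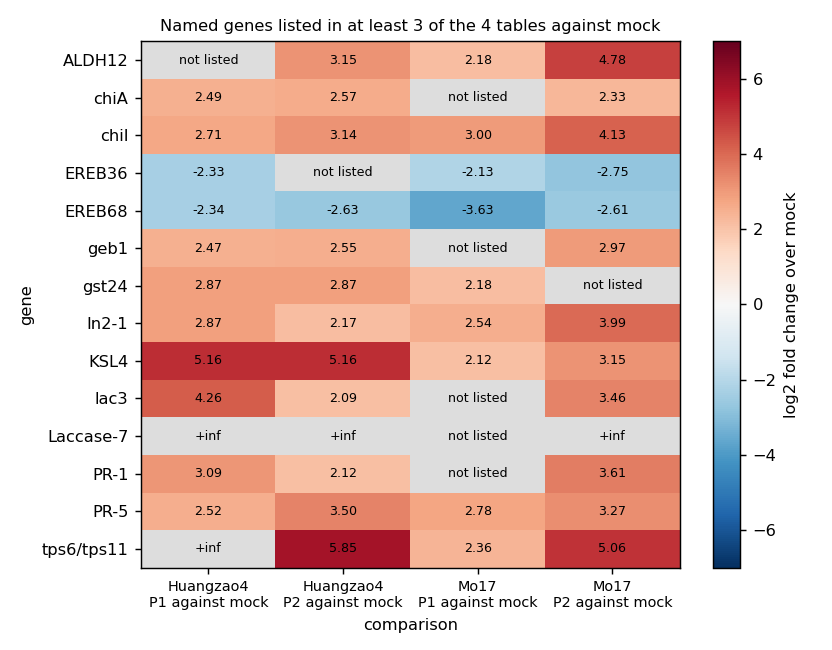
Cells give the log2 fold change over mock in the authors' deposited tables for the 14 named genes listed in at least 3 of the 4 tables against mock, with columns for line and PCR outcome and rows for genes, grey for genes not listed or at an infinite ratio. Of these genes 12 were higher wherever they were listed, and EREB36 and EREB68 were lower.

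Whether both lines moved the same genes was asked by joining the tables of the same contrast, which share no library. Against mock, 53 genes were listed in both lines in P1, and all 53 had the same direction, 47 higher and 6 lower, where 26.7 would share it if directions were drawn from each table's own split. In P2, 86 genes were listed in both lines and 85 had the same direction, 77 higher and 8 lower, against 41.5 drawn in that way. The shared P2 genes included chiI, PR-5, geb1, chiA, KSL4, an2, tps6/tps11, In2-1 and Laccase-7, all higher, and EREB68, lower. In2-1, for example, was at 2.17 in Huangzao4 P2 and 3.99 in Mo17 P2 in the authors' deposited tables. Across all 4 tables against mock, 24 genes were listed, 23 of them higher and 1 lower. The single lower gene was EREB68, and the higher named genes were chiI, PR-5, KSL4, tps6/tps11 and In2-1. With at least 8-fold in both tables the genes with the same direction came to 8 in P1 and 39 in P2, and at p under 0.001 in both tables to 8 and 15. The counts at p under 0.001 do not check the overlap, as the p-values did not line up with their genes. How many genes the authors tested is unknown, so the size of an overlap between unrelated lists is only approximate: over the 34313 protein-coding genes of the reference it would be 2.26 higher and 0.513 lower genes in P1 and 2.12 and 1.55 in P2.

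**Figure D3:**
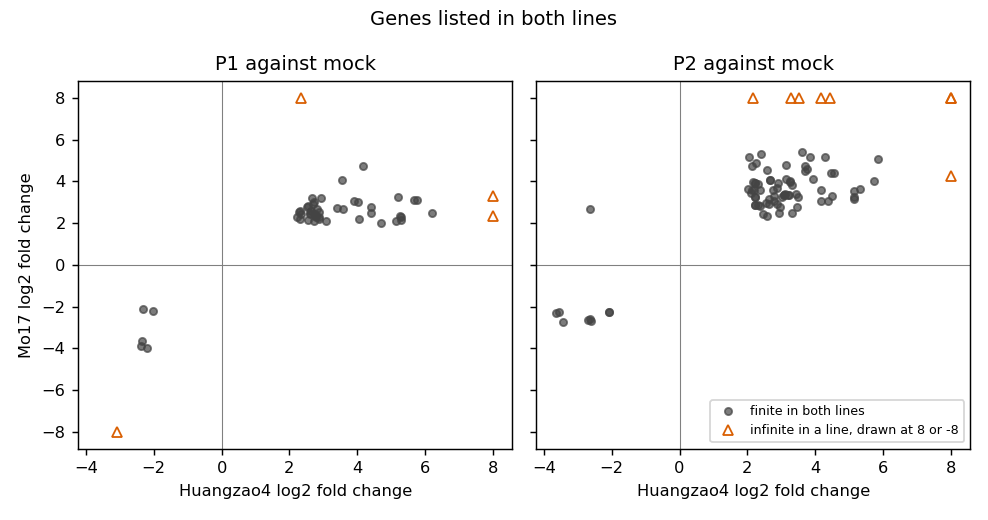
Points are genes listed against mock in both lines, with the log2 fold change of Huangzao4 on the horizontal axis and of Mo17 on the vertical axis, for P1 and for P2, and open triangles for infinite ratios drawn at the edge. All 53 genes of P1 and 85 of the 86 of P2 lie in the quadrants of equal direction.

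Within a line, P1 and P2 were set against the same mock library. In Huangzao4 299 genes were listed in both, 269 higher and 30 lower, with none opposite, and in Mo17 91 genes, 49 higher and 42 lower, with none opposite. For PR-1, which both Huangzao4 tables listed, the authors' deposited tables gave 3.09 in P1 and 2.12 in P2. Part of these overlaps may come from the shared mock library, which could not be simulated without counts, and lists drawn independently would share 5.33 higher and 0.699 lower genes in Huangzao4 and 0.900 and 1.14 in Mo17.

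Set directly against each other, PCR-negative and PCR-positive Huangzao4 roots differed mostly by genes listed higher in P1. RCP1 at 4.42, a value tied with those of GRMZM2G014114 and GRMZM2G020423, the peroxidase gene PER70 at 3.26, the ribosomal protein gene RPS21 at 3.17 and the chitinase gene chiB at 2.87 were higher in P1 in the authors' deposited table. The RPS21 value was tied with that of GRMZM2G008550. Listed at 0 in P2 in the authors' deposited table were the histone gene his1, pdi6, the glutathione transferase gene gst28 and PP2C8, a protein phosphatase gene. Higher in P2 were lg2, the liguleless bZIP gene, at -3.83, the thioredoxin gene trxh2 at -2.10 and bzip1 at -2.08 in the authors' deposited table. Of 3 listed members of the transcription factor list 2 were higher in P1, NAC61 at 2.72 and bHLH108 at 2.19, in the authors' deposited table. The list went by name and did not hold all such genes, lg2 among them. The counts were 337 genes higher in P1, 82.4% of those listed, and 72 lower. Of the genes also listed in P1 against mock, 44 were higher in P1 than in mock and than in P2, and 14 were lower than both. Of the genes also listed in P2 against mock, 66 were higher in P1 than in P2 and lower in P2 than in mock, RCP1, NAC61, bHLH108, his1 and pdi6 among them, but each of these pairs of tables uses the same P1 or P2 library, whose share in this could not be simulated without counts. With p under 0.001, 134 genes were higher in P1 and 17 lower, and the Benjamini-Hochberg threshold kept 90 of 409, with 0 transcription factors left higher at p under 0.001.

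In Mo17 the direct comparison ran the other way, with 43 genes higher in P1 and 112 lower. WRKY111 at -5.06, Laccase-7 at -3.93, TIFY4 at -3.49, PR-1 at -3.31 and whp1 at -2.96 were lower in P1 than in P2 in the authors' deposited table. Higher in P1 were gst19 at 2.65, BX4 at 2.33 and TIFY25 at 2.23 in the authors' deposited table. Detoxification genes split evenly, 2 higher and 2 lower, with gst12 at -3.27 and gst31 at -2.11 in the authors' deposited table. Of the genes also listed in P2 against mock, 45 were higher than mock and lower in P1, and 14 were lower than mock and higher in P1, again with the P2 library in both tables. The counts at p under 0.001 were 6 higher and 27 lower, and the Benjamini-Hochberg threshold kept 4 of 155, with 0 detoxification genes left higher at p under 0.001. The tables of a line did not close: 3 Mo17 genes listed in all 3 tables had P1 minus P2, taken through mock, at -1.03, -1.75 and -1.02, where the authors' deposited table of P1 against P2 gave -2.84, -2.46 and -2.80. The 1 such Huangzao4 gene, GRMZM2G166459, was at 0.196 through mock and at an infinite ratio in the authors' deposited table of P1 against P2.

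Of 25 gene lists, 9 had no listed gene in any table, among them markers of photosynthetic tissue, root hair, root cap and fungal sequences, and 7 had none after correction by hand, which added RPS21 to translation and 3 genes to photosynthesis. These 3, psaN, at -4.48 in Mo17 P2, PSBQ, at -2.82 in Mo17 P1 against P2, and fdx2, at 2.26 in Huangzao4 P2, were missed by the name pattern and stood in the authors' deposited tables. Fungal sequences could not have been found, since every identifier was of maize form and names came from a maize gene table. The root cap list held RCP1 neither before nor after correction. A list without members is therefore not evidence that no such gene was listed.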

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

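Tests chosen only after the result was seen were those of chance agreement, of the Mo17 split and of batch labels for the first pattern below, and that of genes at 0 for the last pattern.

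Opposite directions in the 2 lines were listed for 3 genes, and this difference was not tested. GRMZM2G046952 in P2 against mock was at -2.65 in Huangzao4 and 2.65 in Mo17 in the authors' deposited tables. In P1 against P2, GRMZM2G016290 was at 2.85 in Huangzao4 and -2.71 in Mo17 in the authors' deposited tables. GRMZM2G040734 was at 2.98 in Huangzao4 and -3.16 in Mo17 in P1 against P2 in the authors' deposited tables.

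Nearly all genes listed against mock in both lines moved the same way, 53 of 53 in P1 and 85 of 86 in P2, among them chiI, PR-5, KSL4 and tps6/tps11. Chance alone is argued against, since the share with the same direction exceeded the share expected from the tables by at least 49.7 percentage points. A scaling error of the mock libraries was to be judged by the side on which shared genes fell, but 11.3% in P1 and 9.30% in P2 were lower in both lines, which fell between the bounds set beforehand. The Mo17 tables as a whole speak against it as the sole cause, because at most 50.5% of their genes were higher (95% exact interval 44.9% to 56.0%, counting error only). The Huangzao4 tables leaned to higher genes, with 81.25% in P1 and 63.8% in P2, so the argument rests on Mo17 alone. A handling or batch difference between mock and inoculated roots cannot be told apart from inoculation, as 0 libraries carried a batch or date label, and a response to inoculation stays open as an untested hypothesis.

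Mo17 genes higher than mock in both PCR outcomes had larger fold changes in P2, by a median of 1.03 on the log2 scale over 45 genes (SD 0.669), with 44 of 45 larger. A scaling difference between the 2 tables would move genes lower than mock upward too, and those 38 genes had a median difference of -0.38. To be counted they had to lie beyond 2 in size in both tables, and their median in P1 was -2.43. Genes moved upward past that limit would have left the P2 table, so this value cannot decide on a scaling difference. A rise general to both lines would show in Huangzao4, where the median difference of 238 genes was 0.0799. The failure of the Mo17 tables to close also leaves open other differences in how each table was made. A larger response where the fungus was detected may also account for it, and was not tested, as each outcome had 1 library.

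Huangzao4 P1 against P2 listed 337 genes higher in P1 and 72 lower, RCP1, PER70 and chiB among the former. Loss of low genes to 0 in the P2 library was not the sole source, since 81.4% of genes above 0 in both libraries were higher in P1. Genes that were low in P2 but above 0 could not be set apart without levels, so a loss short of 0 stays open. A scaling difference between P1 and P2 cannot be told apart: the median P1 minus P2 of genes higher than mock was -0.0799, which met the bound set beforehand against it, but that value comes from the tables against mock, which need not carry the scaling of the direct table. The direct table did not follow them for GRMZM2G166459, the 1 Huangzao4 gene in all 3 tables, at 2.71 in P1 and 2.51 in P2 over mock but at an infinite P1 over P2 in the authors' deposited tables, and it was 1 of 4 genes above 0 in P2 against mock but at 0 in P2 against P1, which a factor of scale alone cannot give. A difference between roots with and without detected fungus stays open and untested.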

How the results depend on the processing

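At least 8-fold, leaving out infinite ratios, the Benjamini-Hochberg threshold, the corrected lists and random lists of the same direction were chosen after seeing the data. At p under 0.001, genes higher and lower were 220 and 60 in Huangzao4 P1 against mock, 228 and 85 in Huangzao4 P2 against mock, 134 and 17 in Huangzao4 P1 against P2, 30 and 34 in Mo17 P1 against mock, 47 and 63 in Mo17 P2 against mock, and 6 and 27 in Mo17 P1 against P2. Genes with the same direction in both tables at p under 0.001 were 8 between lines in P1, 15 between lines in P2, 98 within Huangzao4 and 4 within Mo17. Among lists at p under 0.001, pathogenesis-related proteins higher came to 2 in Huangzao4 P1, 3 in Huangzao4 P2 and 0 in Mo17 P1 and in Mo17 P2, and lower ones in Mo17 P1 against P2 to 0. Terpenoid genes higher came to 1 in Huangzao4 P2 and 0 in Mo17 P2. Redox enzymes, ethylene-related genes and ion transport higher came to 1 each in Huangzao4 P1 against mock. In Mo17 P2, lower members at p under 0.001 were 1 benzoxazinoid, 0 jasmonate, 1 ethylene-related and 1 detoxification gene. Lower ethylene-related genes in Mo17 P1 against mock came to 0, higher detoxification genes in Mo17 P1 against P2 to 0, lower transcription factors in Huangzao4 P2 to 1 and higher ones in Huangzao4 P1 against P2 and in Mo17 P1 against mock to 0, and higher jasmonate genes in Mo17 P1 against P2 to 0. Fewer genes pass a stricter p-value by construction, and the deposited p-values did not line up with their genes, so these counts do not check the genes, lists or overlaps. At least 8-fold left 251 higher and 42 lower in Huangzao4 P1 against mock, 206 and 107 in Huangzao4 P2 against mock, 173 and 39 in Huangzao4 P1 against P2, 50 and 61 in Mo17 P1 against mock, 132 and 113 in Mo17 P2 against mock, and 27 and 43 in Mo17 P1 against P2, fewer by construction. Genes with the same direction at 8-fold were 8 between lines in P1, 39 between lines in P2, 141 within Huangzao4 and 19 within Mo17. The Benjamini-Hochberg threshold over the reference genes kept 199, 238 and 90 genes in Huangzao4 P1 against mock, P2 against mock and P1 against P2, and 16, 19 and 4 in Mo17. It ranked listed genes alone, so these counts may be too low, and they would not hold if the p-values were already adjusted. With corrected lists, Huangzao4 P1 had 4 redox enzymes, 1 ethylene-related gene, 5 transport genes and 0 seed storage markers higher, and terpenoid genes higher were 4 in Huangzao4 P2 and 4 in Mo17 P2, because members were added or removed. Over all lists, those with fewer than 2 listed members included, correction moved 36 of 84 counts by over 1.5 times, 34 of them upward. Against random lists of the same direction, the percentile of pathogenesis-related proteins was 14.2 in Huangzao4 P1, 14.8 in Huangzao4 P2 and 33.7 in Mo17 P2, and that of ethylene-related genes in Mo17 P2 was 79.5, since direction no longer counts. All 17 counts without infinite ratios stayed within 1.5 times. At least 4-fold (42 counts) and a log2 shift of 0.5 in either direction (12 counts each) changed nothing, since every listed gene lay beyond 2, and so say nothing of stability. A mean level of at least 50 and pseudocounts of 1 and 10 were not run, as the tables held no levels. No paired analysis was possible because the tables held filtered fold changes and no levels per library. The depth of the libraries is unknown, but from 18.2% of finite fold changes in Mo17 P1 against P2 to 55.1% in Huangzao4 P1 against P2 were tied with another gene's, and the cause was not tested. Tied named genes included MYBR58, bHLH108, hap2 and NIP1-1 in Huangzao4 P2 against mock and RPS21 in Huangzao4 P1 against P2. Some untied values had the same digits after the point, as MYBR58 at 4.6885 and PP2C8 at 3.6885 in Huangzao4 P1 in the authors' deposited table. So did RCP1 at 4.41954 and GRMZM2G034956 at 3.41954 in Huangzao4 P1 against P2 in the authors' deposited table. Whether such values, those of named genes included, rest on few tags could not be checked without counts.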

Other observations

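The count of close identifiers and the test of the p-values were chosen after the patterns were seen.

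Further named genes were listed for both PCR outcomes of Huangzao4 against mock. The authors' deposited tables gave the germin-like gene GLP2 3.12 in P1 and 3.73 in P2, the AP2/ERF gene EREB179 3.32 and 2.83, and the aquaporin gene NIP1-1 3.37 and 3.17. The hemoglobin gene Hb at 3.66 and the alcohol dehydrogenase gene adh2 at 2.20 were higher in Huangzao4 P1 in the authors' deposited table. In both lines dxr, of the methylerythritol phosphate pathway, was higher, at 2.17 in Huangzao4 P1 and 2.77 in Mo17 P2 in the authors' deposited tables. The wound-induced inhibitor gene wip1, at 4.76 in Mo17 P2, was at 2.15 in Huangzao4 P2 in the authors' deposited tables. EREB179, Hb, adh2 and dxr fall outside the naming rule and were chosen after their values were seen.

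Some genes with neighbouring identifiers had exactly equal fold changes, such as Hb and GRMZM2G067419 in Huangzao4 P1, and HAK5 and GRMZM2G084774, both at 3.03, in Huangzao4 P2 in the authors' deposited tables. A candidate explanation is that such identifiers shared tags or were parts of 1 locus. Pairs with identifiers at most 50 apart made up 4.31% of 627 pairs with equal fold changes and 0.0665% of all pairs of the same direction, a ratio of 64.8. The ratio measures the pattern itself and does not test this explanation, nor does it separate shared tags from neighbouring copies. Of the 21 different pairs 0 had both genes in the reference, so their places could not be compared. Of 15441 neighbours in identifier order at most 50 apart in the reference, 485 lay within 100 kb, 3.14%, so close identifiers were seldom close in that assembly. The share for gene pairs taken at random was not computed, so this value does not weigh against neighbouring copies.

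If p-values stood beside the genes they were computed for, neighbouring rows with equal p-values would mostly have equal fold changes, and 25.8% did, which argues against it.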
